A study of Mus musculus with 2 samples.

How the data were processed

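RNA sequencing was carried out on CD8 T cells of the mouse strain C57BL/6, 1 library from wild-type and 1 from DGKζ-deficient animals. Per the labels' protocols, naive CD8 T cells were isolated from spleen with a commercial kit, cultured for 24 hours on plate-bound antibodies against CD3 and CD28, and lysed in Trizol, and libraries were made with the NEBNext Ultra RNA kit. That kit does not mark the strand of origin, so reads of a gene and of an overlapping antisense gene cannot be told apart. The labels give an age of 7 weeks for the wild-type and 6 weeks for the deficient animals. They give no sex, no number of animals per library and no sequencing batch.

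Per the submitters' processing notes, STAR version 2 and DESeq were used and the genome build was mm9, with no role or order stated. The counting program and the annotation release are not given in the sources used here. The authors deposited 1 table of normalized read counts, a never-negative signal per RefSeq transcript row and library, which is the read count divided by 1 size factor per library. The values were checked for steps. In both libraries, 100% of the values were whole multiples of the smallest value above 0, within a relative tolerance of 0.0001, so whole reads were recovered. The size factors recovered in this way were 1.71 for the wild-type and 0.583 for the deficient library, and a single read was worth 0.583 and 1.71 normalized counts. The authors deposited a second table with a log2 fold change, a test score, a p-value and an adjusted p-value per transcript row. The log2 and p-values of that table are quoted only as the authors' deposited values, and its score was not used here. The files carry no coordinates, and the annotation at hand is of another build than mm9, so no positions are given.

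The table held 33018 transcript rows. In 1 row, that of Alg6, an additional tab shifts the values, and it was left out. In 53 rows the gene symbol has been turned into a date by spreadsheet software, and these rows kept the deposited name. Of 24013 gene symbols, 4911 had several transcript rows, and reads shared by transcripts of a gene appear to be counted in more than 1 of its rows. The row with the highest mean of both libraries therefore stood for each gene, a choice made after the files had been seen, since values per gene had been assumed. With 1 row per gene the wild-type library held 37211969 and the deficient library 13464169 reads, a ratio of 2.76, and over all rows they held 55330091 and 19814735. The pre-ribosomal RNA Rn45s took 2.81% and 2.53% of the reads.

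The labels give 1 library per genotype, so no difference has a replicate check, no p-value across genes was computed, and edgeR's quasi-likelihood test on the recovered reads has no residual degrees of freedom. Each gene is described by its normalized counts in both libraries and by log2((deficient + 10)/(wild type + 10)), called the log2 ratio. The pseudocount of 10 normalized counts understates the change of low genes. Folds are ratios of the normalized counts without a pseudocount, each with an exact 95% interval (Clopper-Pearson, on the share of the deficient library among the reads of the gene in both). These intervals cover counting error only, and reads without molecular identifiers are not independent molecules. Where a library held 0 reads, the fold is a lower bound against 3 reads in that library. Genes with a mean of at least 50 normalized counts were compared, 10518 in all, and a gene is called 2-fold higher or lower where its log2 ratio reached 1 or -1. Counts of genes at least 2-fold different use that rule. Some uncalled genes therefore have a fold above 2 without the pseudocount, among them Ier3 (2.04-fold higher), Ccnb2 (2.01-fold higher) and Bcl6 (2.14-fold lower).

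The 33 gene lists, the thresholds and the rule for naming genes were fixed before the data were examined. The rule names Dgkz, the 15 genes with the highest and the 15 with the lowest log2 ratio apart from 5 sex-linked genes, the 4 members of each list with the largest absolute log2 ratio, and every called member where a list has 5 or fewer in a direction. Some genes that the rule names are not reported here. Genes named outside this rule were chosen after their values were seen. In the comparison these are Rasgrp1, Ifng, Serpinb9, Ccl9, Lta, Gzmb, Prf1, Nkg7, Rcan1, Atf4, Slc1a5, Malat1, Rmrp and Ccr7. For each list with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is called above or below where its median left the central 95% of those random medians. The sex-linked list was not placed in this way, and its genes were kept out of the random lists. This describes the 2 libraries. Genes of a list are not independent replicates, so lists leave that range more often than the 95% implies.

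The procedures were tested on simulated data with the real means and read totals and counting noise alone. Of 50 genes changed 3-fold, 100% were called, as were 100% of those changed 4-fold and 8-fold, and 0% of those changed 1.5-fold. Of 10323 unchanged genes 0 were called, and 1 of 25 lists without a planted change left the central 95%. Alternatives covered the pseudocount, the expression minimum, the fold threshold, the scaling between libraries (recentring, equal totals, upper quartile and TMM), the choice of transcript row, list composition, random lists without matching, and removal of a trend with transcript length and GC content. Length and GC content came from GENCODE M21 transcripts matched by RefSeq accession or symbol and were found for 99.6% of the compared genes. The trend was fitted by lowess with a span of 0.3. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, R 4.3.3 and edgeR 4.0.16 (for TMM) were used.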

Results

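The transcriptome of splenic CD8 T cells was measured after 24 hours of stimulation through CD3 and CD28, in 1 library from wild-type mice and 1 library from mice lacking diacylglycerol kinase ζ (DGKζ). DGKζ phosphorylates diacylglycerol, the second messenger that couples the T cell receptor to RasGRP1, Ras and protein kinase C, and thereby limits that branch of signalling. The single comparison of the design asks which transcripts of stimulated CD8 T cells differ between the genotypes. The libraries held 37211969 (wild type) and 13464169 (deficient) reads over 24013 genes. There is 1 library per genotype, so every difference below lacks a replicate check. The libraries also differed in age and, by their sex-linked transcripts, in sex, so no difference below can be assigned to genotype alone. The intervals given cover counting error only, not variation between animals or cultures.

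Dgkz, the targeted gene, was read at 6714 normalized counts in the wild-type library and 2591 in the deficient library. It was 2.59-fold lower in the deficient library (95% counting interval 2.46 to 2.74), and its 2 transcript rows gave the same log2 ratio of -1.37. The table counts reads over whole transcripts and the labels do not state which exons are deleted, so the remaining 1511 reads cannot be assigned to deleted or retained parts of the gene. Of the other kinases of the family, Dgka, the second main isoform of T cells, stood at 3908 and 2461 normalized counts, 1.59-fold lower (1.5 to 1.68). The wider list of diacylglycerol kinases and effectors had a median log2 ratio of -0.083, just below the range of matched random lists (-0.058 to 0.18), and was no longer below it without genes of other lists or with unmatched random lists. Its value lay between -0.043 (length and GC trend removed) and -0.17 (equal totals, or no expression minimum) where it stayed below. Of its 22 measured members, 1 (Dgkz itself) was at least 2-fold lower and 21 were not called. Prkd2 (protein kinase D2) had a log2 ratio of -0.78 and Plcg2 one of 0.70, while Rasgrp1, the Ras activator that binds diacylglycerol, was read at 2601 and 2536 normalized counts.

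As lists, cytokine and stress-response genes were higher and trafficking receptors lower in the deficient library, the receptors with members in both directions. Of the 10518 genes compared, 137 were at least 2-fold higher and 136 at least 2-fold lower in the deficient library, together 2.60% of them. Scaling both libraries to equal totals changed this split to 115 higher and 179 lower. The median log2 ratio of all compared genes was 0.055, with quartiles at -0.14 and 0.22. Apart from the 5 sex-linked genes, the highest log2 ratio belonged to Tsix, which lies antisense to Xist and cannot be separated from it in unstranded reads. Next came Cth (cystathionine γ-lyase), read at 40.2 and 760 normalized counts, 18.9-fold higher (14.6 to 24.7). Tagap1, at 161 and 1617, has a close paralog, so its reads are uncertain. Others among the 15 highest were Trib3, Il2, Slc7a3, Chac1, Batf3, Asns, Wdfy1, Gpt2, Slc7a11, Pck2 and Il3. Of these, Wdfy1 depended on the transcript row, with log2 ratios from 1.34 to 2.62.

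At the other end, Rab6b (a small GTPase) was read at 348 and 13.7 normalized counts, 25.4-fold lower (12.8 to 59.0). Trim13 had 186 reads in the wild-type library and 0 in the deficient one, at least 21.1-fold lower against 3 reads. Ccr9, the gut-homing chemokine receptor, was 9.34-fold lower (5.77 to 16.2). Klf2, a transcription factor that maintains quiescence and S1pr1 expression in naive T cells, was 4.81-fold lower (3.39 to 7.03). Egr3, an early growth response transcription factor, was 3.72-fold lower (3.27 to 4.27), at 1552 and 417 normalized counts. Hivep3 was the most abundant of the 15 lowest genes, at 4941 and 1250. The other genes of that group were 2610035D17Rik, Sfn, Pydc3, Gm14085, G530011O06Rik, Zfp948, Synpo, Prr12 and Mid1. Pydc3 and Gm14085 belong to families of near-identical copies, and their values are uncertain for that reason.

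**Figure D1:**
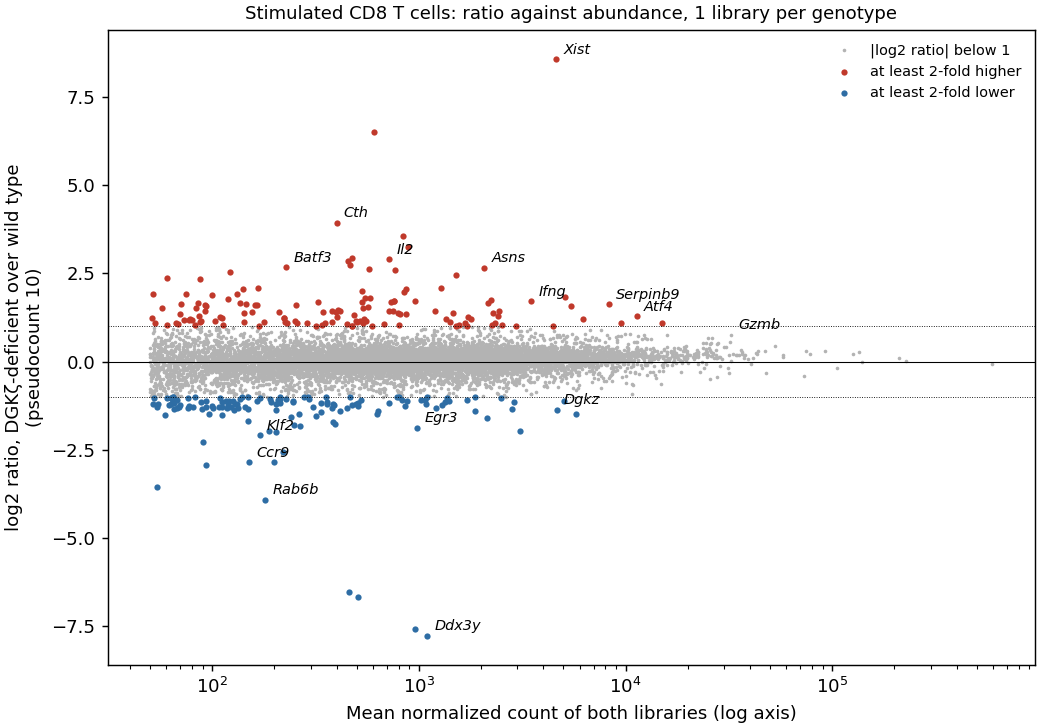
Log2 ratio of the DGKζ-deficient over the wild-type library (y axis, pseudocount 10) against the mean normalized count of both libraries (x axis, log scale) for the 10518 compared genes, 1 point per gene. The 137 red genes were at least 2-fold higher and the 136 blue genes at least 2-fold lower in the deficient library, and dotted lines mark log2 ratios of -1 and 1.

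The list of effector cytokines, chemokines and cytotoxic genes was higher in the deficient library. Il2, the growth factor of activated T cells, was read at 162 and 1274 normalized counts, 7.86-fold higher (6.84 to 9.05). Ifng, the signature cytokine of CD8 effector cells, was 3.29-fold higher (3.12 to 3.46), at 1629 and 5356. Of 29 members of this list 17 were measured, of which 8 were at least 2-fold higher, 0 lower and 9 not called, and its median log2 ratio of 0.77 lay above all 10000 random lists. Without an expression minimum the median was 0.12, above 99.1% of random lists. The other called members were Il3, Csf2, Serpinb6b, Serpinb9, Ccl9 and Lta. Serpinb9, an inhibitor that protects T cells from their own granzyme B, was 3.10-fold higher (2.99 to 3.20). Il3 and Csf2 rested on few reads, 22 and 27 in the wild-type library. Of the cytotoxic genes, Gzmb (granzyme B) had a log2 ratio of 0.77, whereas perforin (Prf1) and Nkg7 had log2 ratios of -0.34 and -0.32.

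Genes driven by NF-κB were higher as a list, with a median log2 ratio of 0.55 above all random lists. Of the 19 measured members, 18 had a log2 ratio above 0, but only Cd83 (2.77-fold, 2.47 to 3.09) and Nfkbia (2.01-fold, 1.90 to 2.12) were called higher. Nfkbia encodes the inhibitor that NF-κB induces as its own feedback, and Tnfaip3, another such feedback gene, was 1.92-fold higher (1.78 to 2.07). Icam1 had a log2 ratio of 0.97.

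Targets of calcium and NFAT signalling were lower as a list. Their median log2 ratio was -0.55, below all random lists. Of 14 measured members, 4 were at least 2-fold lower, 0 higher and 10 not called. The called members were Egr3, Nr4a2 (2.30-fold, 1.96 to 2.71), Nfatc1 (2.21-fold, 2.07 to 2.36) and Tnfrsf9, the costimulatory receptor 4-1BB (2.19-fold, 2.09 to 2.30). Rcan1, a calcineurin feedback gene, was read at 223 and 225 normalized counts.

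The list of ERK and AP-1 targets, the genes most directly downstream of diacylglycerol and Ras, had members in both directions, 11 of 25 above 0. Its median log2 ratio of -0.018 lay inside the range of random lists (-0.085 to 0.17), while its mean of -0.15 lay below that of random lists. Of its 25 measured members, Egr3, Spry2 and Egr1 were called lower, 0 were called higher and 22 were not called. Egr1, an immediate early gene, was 2.03-fold lower (1.83 to 2.26), and Spry2, a feedback inhibitor of the pathway, 3.19-fold lower (2.14 to 4.93). Ier3 had a log2 ratio of 0.95 and was not called, while it was 2.04-fold higher (1.56 to 2.65) without the pseudocount. Egr3 is a member of both this list and the calcium list.

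The largest median of any list belonged to the ATF4 and amino acid stress genes, a program of amino acid synthesis, transport and stress signalling. The median log2 ratio was 1.18, above all random lists (central range -0.057 to 0.19). Of 22 measured members, 12 were at least 2-fold higher, 0 lower and 10 not called. Asns, asparagine synthetase, was read at 558 and 3581 normalized counts, 6.42-fold higher (5.94 to 6.93). Cth was joined by Trib3 (8.30-fold, 6.97 to 9.92), Slc7a3, a cationic amino acid transporter (7.84-fold, 6.58 to 9.37), and Chac1, a glutathione-degrading enzyme (7.19-fold, 6.08 to 8.54). Atf4, the transcription factor itself, was 2.44-fold higher (2.38 to 2.51), at 6564 and 16042. Slc1a5, the glutamine transporter, was the 1 member with a log2 ratio below 0, at -0.40.

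Cell division genes differed by phase. All 25 measured G2/M genes had a log2 ratio above 0, with a median of 0.72 above all random lists. Only Nusap1 was called higher (2.05-fold, 1.93 to 2.18). Ube2c, Ccnb2 and Hmmr had log2 ratios of 0.99, 0.98 and 0.97, and Ccnb2 was 2.01-fold higher (1.77 to 2.28) without the pseudocount. The 28 G1/S and replication genes had a median of 0.077 inside the random range, with 0 called, and that median was -0.013 when libraries were scaled to equal totals. Rrm1, Rrm2, Ccne1 and Tyms had log2 ratios of 0.39, 0.35, 0.32 and 0.32. In the list of non-polyadenylated RNAs, chosen as a sign of RNA selection, the histone genes Hist1h2ab, Hist1h2bc, Hist1h1c and Hist1h3b had log2 ratios from 0.63 to 0.76. The non-histone RNAs Malat1 and Rmrp stood at -0.33 and -0.18 in that list, and its median was 0.54, above all random lists, with 0 of 9 members called. Its mean of 0.25 did not leave the range of random lists. The mitochondrial transcripts, another list on RNA quality, had 0 members with a mean of at least 50, so that list gave no check of RNA quality.

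Of the metabolic lists, those of glycolysis and hypoxia and of sterol and fatty acid synthesis were above the random range. Glycolysis and hypoxia genes had a median log2 ratio of 0.42, above all random lists, with 3 of 23 members at least 2-fold higher and 0 lower. These were Vegfa (3.58-fold, 3.15 to 4.08), the hypoxia-induced hydroxylase gene Egln3 (2.66-fold, 2.39 to 2.96) and the lactate exporter gene Slc16a3 (2.59-fold, 2.34 to 2.86), and Bnip3 had a log2 ratio of 0.79. Sterol and fatty acid synthesis genes had a median of 0.22 (0.13 at equal totals), above 99.5% of random lists. The desaturase genes Scd1 (3.31-fold, 2.96 to 3.71) and Scd2 (2.12-fold, 2.07 to 2.18) were called among 24 members, Fdps had a log2 ratio of 0.68 and Fasn one of -0.44. Oxidative phosphorylation genes (median 0.16, 0 of 27 called) and ribosome biogenesis and MYC targets (median 0.15, 0 of 26 called) lay inside the random range. At equal totals these medians were 0.067 and 0.063, and the first was 0.073 with the length and GC trend removed. In these 2 lists the largest log2 ratios were 0.42 for Uqcrq, 0.32 for Cox4i1, 0.31 for Sdhc and Atp5b, -0.47 for Cad, 0.43 for Nip7, 0.38 for Odc1 and 0.37 for Rrp9.

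Genes of the naive and quiescent state were lower as a list, with a median log2 ratio of -0.30 below all random lists, in the same library in which the B cell markers had a median of -0.77. Klf2 and its target S1pr1 (2.38-fold lower, 1.98 to 2.88) were called among 23 members, 0 were called higher and 21 were not called. Pik3ip1 and Bach2 had log2 ratios of -0.71 and -0.68. The lymph-node homing receptor gene Ccr7, also on this list, had a log2 ratio of 0.55. The chemokine and trafficking receptors had a median of -0.57, below all random lists. That median was -0.18 at a minimum mean of 200 and -0.23 without a minimum, and the mean was -0.28, each still below the central 95% of random lists but not below all of them. Ccr9 and S1pr1 were called lower, 1 member was called higher, 9 of 12 were not called, and Cxcr5 had a log2 ratio of -0.86. Of the 12 members, 4 had a log2 ratio above 0. T cell receptor signalling genes had a median of -0.18, below all random lists, with 0 of 23 called. Cd3g, Cd8a, Zap70 and Cd3e had log2 ratios of -0.87, -0.63, -0.49 and -0.48. TGF-β pathway and integrin genes had a median of -0.18 (-0.088 with the length and GC trend removed), with 0 of 21 called. Itgae (CD103) had a log2 ratio of -0.84, Tgfb1 -0.57, Icam1 0.97 and Itgb1 0.63.

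Among activation and costimulatory receptors, Cd44 (2.73-fold, 2.57 to 2.90) and Tnfrsf4, encoding OX40 (2.63-fold, 2.47 to 2.80), were higher and Tnfrsf9 was lower, 14 of 17 were not called, and Slc3a2 had a log2 ratio of 0.74. The median of 0.21 lay inside the random range (-0.031 to 0.21), close to its upper end, and left it upward under 5 of the alternatives. The inhibitory receptors had a median of -0.0085, also inside, with 0 of 14 called, and their mean of 0.0058 had the opposite sign. Ctla4 had a log2 ratio of 0.86, Cd200 0.77, Cd160 -0.77 and Ptpn22 -0.63. Of the effector and memory transcription factors, Batf3 alone was called (7.40-fold higher, 5.80 to 9.51) among 17 members with a median of 0.12 inside the random range and a mean of 0.35 above it. Eomes had a log2 ratio of 0.95, Bcl6 -0.94 and Bhlhe40 0.86. Interferon response genes had a median of 0.16, inside the random range but above it at the other expression minimums, and 4 of 25 were called higher: Isg15 (3.51-fold, 2.68 to 4.60), Usp18 (2.75-fold, 2.38 to 3.19), Oas3 (2.24-fold, 1.96 to 2.56) and Oasl2 (2.54-fold, 1.66 to 3.87).

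Apoptosis regulators had a median log2 ratio of 0.23 (0.14 at equal totals), above 99.6% of random lists. The pro-apoptotic gene Bcl2l11 (BIM) was 2.66-fold lower (2.44 to 2.90) and the death receptor gene Fas 2.71-fold higher (2.33 to 3.15; log2 ratios from 0.75 to 1.40 by transcript row), while 19 of 21 were not called. Bcl2a1d and Bbc3 had log2 ratios of 0.86 and 0.72. This median was -0.075 when genes shared with other lists were left out, and inside the random range when the length and GC trend was removed. The p53 targets had a median of 0.34, with Sesn2 (3.61-fold, 3.16 to 4.13), Fas and Cdkn1a (2.58-fold, 1.82 to 3.65) called higher among 17 members, 0 lower, and Trp53inp1 at -0.94. Sesn2 is also on the ATF4 list. Left without genes of other lists, the p53 list had a median of 0.14 and was no longer above the random range. Cytokine receptors had a median of 0.032 inside the random range, with 0 of 15 called, and that median was -0.057 at equal totals and -0.022 after recentring. Ifngr2, Il15ra, Il10ra and Il6st had log2 ratios of 0.83, 0.80, 0.76 and -0.58.

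**Figure D2:**
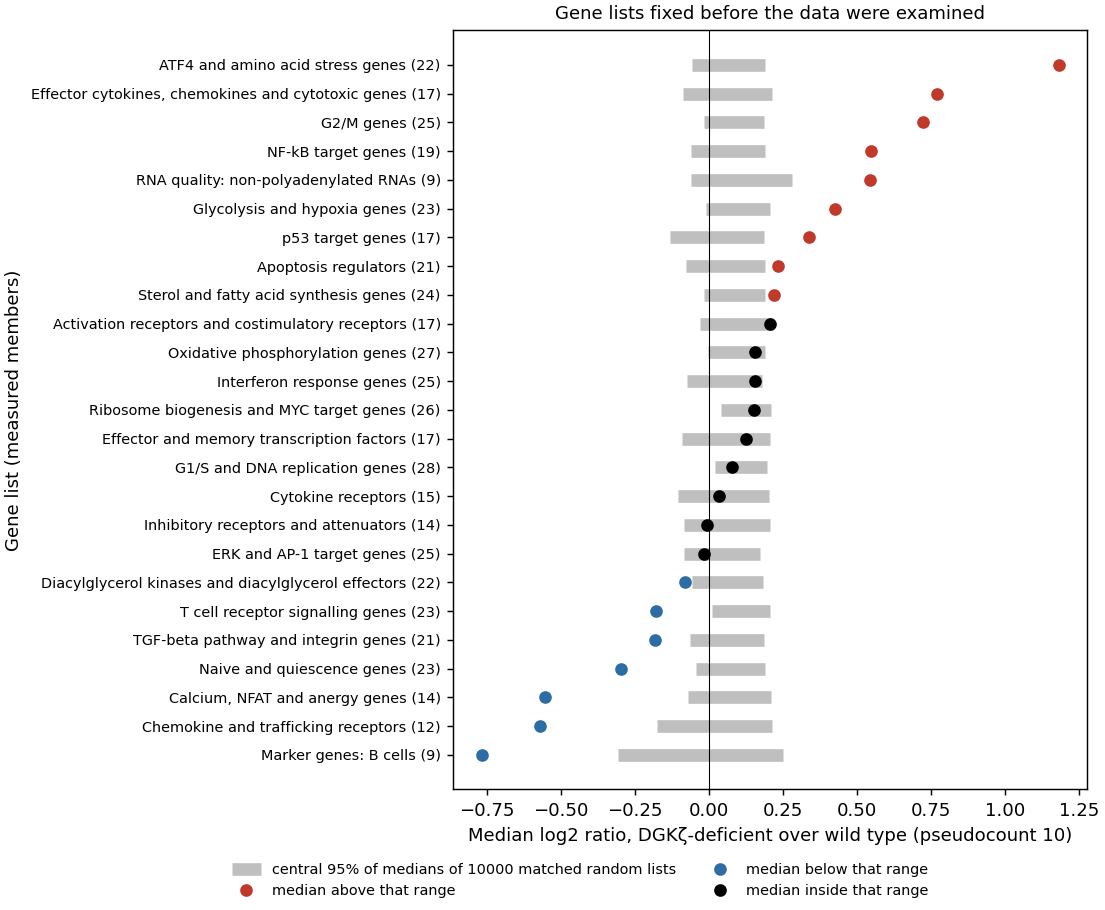
Median log2 ratio (x axis, deficient over wild type, pseudocount 10) of the 25 gene lists other than the sex-linked list with at least 5 measured members (y axis, number of measured members in brackets). Grey bars span the central 95% of medians of 10000 random lists matched on expression; 9 lists lay above it (red), 7 below it (blue) and 9 inside it (black), and the ATF4 list stood highest at 1.18.

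**Figure D3:**
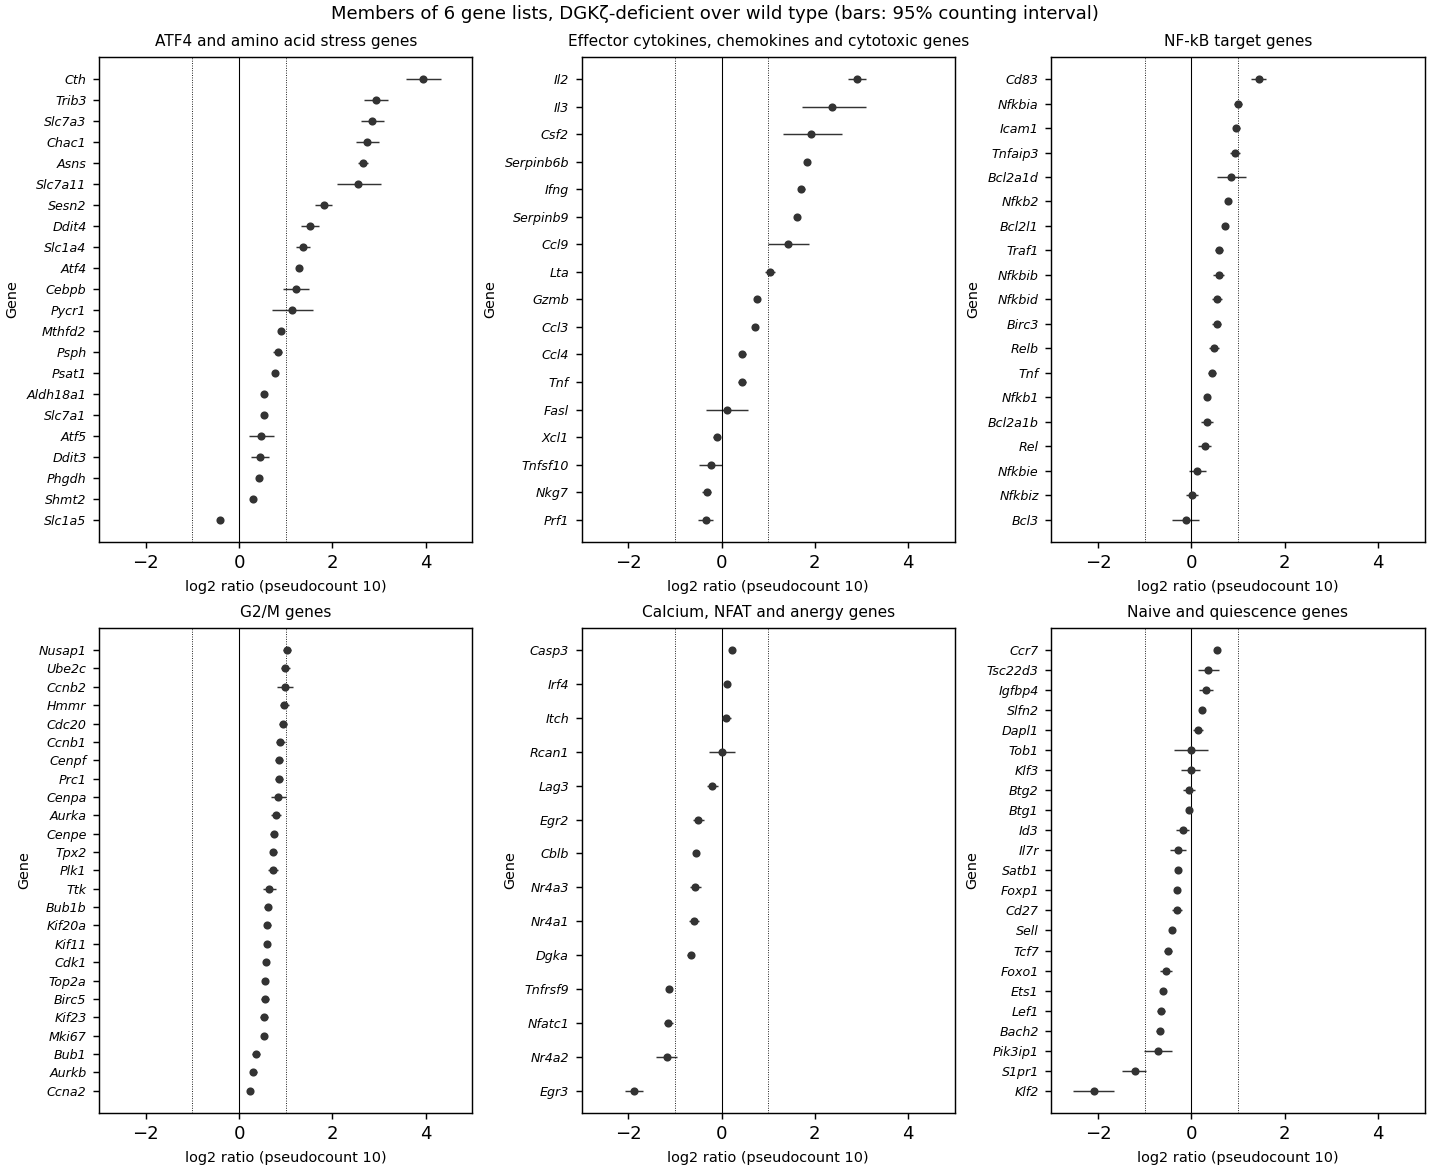
Log2 ratio (x axis, pseudocount 10) of each measured member (y axis) of 6 gene lists, with the 95% counting interval of the ratio, put on the same pseudocount scale, as a bar and dotted lines at -1 and 1. All 25 G2/M genes lay above 0, 12 of 22 ATF4 genes lay above 1, and 4 of 14 calcium and NFAT genes lay below -1.

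Some genes on the marker lists of other cell types differed between the libraries. Whether the CD8 T cells themselves expressed them was not tested. The B cell list had a median log2 ratio of -0.77, below all random lists, with all 9 measured members below 0, while fewer than 5 members reached a mean of 200. Of the 9 members, 2 were called lower, H2-Eb1 (2.31-fold, 1.79 to 3.03) among them, and Ms4a1 and H2-Aa had log2 ratios of -0.85 and -0.83. H2-Eb1 was read at 269 and 117 normalized counts, against 13090 and 8455 for Cd8a. Cd4 was 3.21-fold lower (2.22 to 4.82), at 171 and 53.2, while Foxp3 stood at 262 and 321 and Zbtb7b at 57.1 and 48.0. Of the 10 genes on the NK and innate-like list 2 were measured. Klrd1 was 2.95-fold lower (2.33 to 3.78) and Klrk1 was read at 587 and 633 normalized counts. Mpeg1 and Cd68 were the 2 myeloid markers measured, with log2 ratios of 0.52 and -0.37. Of the 9 genes on the endothelial and stromal list, only Pecam1 was measured, at 1015 and 676 normalized counts (log2 ratio -0.58). That single gene does not show that endothelial cells were present. The lists of neutrophil and mast cell markers and of erythroid and platelet markers had 0 members with a mean of at least 50. The naive, T cell receptor and trafficking lists were lower in the same library as the B cell and Cd4 markers.

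Sex-linked genes differed most between the libraries. Xist, the RNA of the inactive X chromosome, was read at 14.0 and 9206 normalized counts, 658-fold higher in the deficient library (442 to 1028). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 2192, 1911, 1012 and 921 normalized counts in the wild-type library and 0 reads in the deficient library. Against 3 reads they were at least 426-fold, 371-fold, 197-fold and 179-fold lower. The wild-type library thus read as from a male source and the deficient library as from a female source, although the labels give no sex. Sex and age of the animals differed together with genotype, and their effects cannot be told apart from it here.

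The authors' deposited table of this comparison listed 0 of 30433 tested rows at an adjusted p below 0.05, and its lowest adjusted p was 0.999. At an unadjusted p below 0.05 the authors' deposited table held 326 rows, 174 higher and 152 lower in the deficient library, from 204 gene symbols. With 1 library per genotype, the dispersion behind its p-values cannot come from replicates within a genotype. Those p-values therefore do not show that genes were unchanged. The deposited log2 fold changes lay between -0.66 and 0.67. For all 273 genes called here they had the same sign as the log2 ratio. Both rest on the same counts, so that match is no independent check. The authors' deposited table gives Dgkz a log2 fold change of -0.20, Il2 0.12, Asns 0.13 and Xist 0.04.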

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

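Of the alternatives, the removal of a length and GC trend and the other choices of transcript row were added after the data were seen. The count of genes at least 2-fold higher (137) stayed within 1.5 times under every pseudocount, expression minimum and scaling run. The count of lower genes (136) was 67 with a pseudocount of 50, 247 and 71 with a minimum mean of 10 and 200, and 375 without a minimum. After removal of the length and GC trend the lower count was 108, while the higher count stayed at 137. The cause of these changes was not tested. At a threshold of 1.5-fold there were 476 higher and 533 lower genes, and at 3-fold 49 and 22. All 273 called genes had a counting interval that excluded equality, and 251 of them stayed called at equal totals and 223 after removal of the length and GC trend. The log2 ratio of Dgkz (-1.37) was -1.46 at equal totals and -1.21 after removal of the trend. The 9 lists above and 7 below the random range became 8 to 10 and 6 to 8 over all alternatives. The median of the apoptosis regulators was -0.075 without genes of other lists, and the cause was not tested. No other called list changed direction. The authors' deposited table held 0 rows below adjusted p thresholds of 0.1 and 0.01. With 1 library per genotype, no library could be left out. No paired analysis was possible because each genotype has 1 library.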

Other observations

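The tests on transcript length, on X-linked genes and on the neighbours of Dgkz were set before their results were seen, and the test on abundant ATF4 genes and the statement on single libraries after.

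Genes outside the fixed lists, apart from Gpt2 and Pck2 chosen after their values were seen, add to the account. Gpt2 (alanine aminotransferase, 6.33-fold, 5.58 to 7.20), Pck2 (mitochondrial phosphoenolpyruvate carboxykinase, 5.57-fold, 5.10 to 6.07), Atf3 (4.27-fold, 3.83 to 4.76), the glycine transporter gene Slc6a9 (3.39-fold, 2.86 to 4.03) and Eif4ebp1, an inhibitor of cap-dependent translation (3.21-fold, 3.01 to 3.43), were higher in the deficient library and are known from amino acid stress responses. Kmt2d, a histone methyltransferase, was 3.05-fold lower (2.81 to 3.32). Prrc2a was 2.83-fold lower (2.69 to 2.98). Neither fold was corrected for the trend with transcript length given below.

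The ATF4 and amino acid stress genes were the list furthest from the random range. Long transcripts were lower in the deficient library, from a median log2 ratio of 0.15 in the shortest 10% of genes to -0.075 in the longest 10%. Removing that trend together with GC content left the ATF4 median at 1.20, outside the random range of -0.043 to 0.19, which argues against it as the cause. Counting noise of low genes is argued against by the 10 members with a mean of at least 1000, whose median was 0.65 against a random range of -0.033 to 0.26. A difference between the animals or culture wells other than Dgkz may account for the pattern, and cannot be told apart from the genotype with 1 library per genotype.

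The calcium and NFAT list moved against the NF-κB and cytokine lists. After removal of the length and GC trend its median was -0.50, still below the random range of -0.044 to 0.21, which argues against that trend as the whole cause. Genotype, sex and age stay open as sources of the difference, and no biological explanation was tested.

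Sex and strain background are candidate sources of part of the remaining differences. Among X-linked genes, 5 known to escape inactivation (Kdm6a, Kdm5c, Eif2s3x, Ddx3x and Utp14a) had a median log2 ratio of 0.57, above the random range of other X-linked genes (-0.30 to 0.30), as a female source of the deficient library and a male source of the wild-type library would give. How far sex accounts for autosomal differences stays open. Knockout alleles can carry flanking DNA of another strain, but of the 60 measured genes nearest to Dgkz 16.7% had an absolute log2 ratio of at least 0.5, between the median (11.7%) and the 95th percentile (20%) of 163 windows elsewhere, which leaves that open. Cd44, 2.73-fold higher, is among those neighbours. Atp10d, of which the C57BL/6 reference carries a truncated allele, was read at 482 and 2068 normalized counts, 4.29-fold higher (3.93 to 4.70) in the deficient library. Atp10d is not among those neighbours and was chosen after its value was seen, so it does not bear on the segment around Dgkz.

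In the authors' deposited table the size of the log2 fold change followed the ratio of the authors' own normalized counts for small differences but not for large ones. Among genes with a mean of at least 1000, the 3277 with an absolute log2 ratio below 0.25 had a median deposited value of 0.088. That median was 0.24 for ratios from 0.25 to 0.5 and 0.44 for ratios from 0.5 to 1. The 48 genes with a ratio from 1 to 2 had a median of 0.21 and the 5 with a ratio of at least 2 one of 0.13. A ranking by the deposited values or p-values therefore places Xist and Asns behind genes with smaller differences. The cause was not tested.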
